A study of Rattus norvegicus with 48 samples.

How the data were processed

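Epididymal sperm DNA of Sprague-Dawley rats was measured by reduced representation bisulfite sequencing in 48 samples, of which the labels assign 6 to each of 8 groups defined by labelled generation and treatment. Libraries were made from sperm DNA with a gel-free protocol and bisulfite conversion, per the labels' protocols. The submitters' processing notes name CASAVA, Trim Galore 0.4.0, Bismark 0.14.5, SAMtools 1.2, bedtools 2.17 and methylKit 0.9.4 and the rat build Rnor_5.0, with no role or settings. The coverage minimum, the treatment of strands and the model used are not given in the sources used here.

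The deposited files are 6 lists of cytosines, each with a position, a strand, a signed methylation difference, a p-value and a q-value calculated by the authors. The authors kept sites with a false discovery rate below 1% and a minimum methylation difference of 20 percentage points, per the description deposited with the lists. The difference is the authors' contrast of 2 groups in percentage points, so values of single samples, group levels and coverage were not analysed here and the depth of each sample is unknown. The deposited p-value was listed at 0 for 2105 sites. No error or number of replicates can be attached to a listed difference, and the tests made here treat the lists as given.

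The lists are described as generations F1, F2 and F3, the labels number generations 1 to 4, and the samples whose labels cite the lists carry the numbers 2, 3 and 4. The comparisons are therefore named as the lists name them, and no list was tied to single samples. Lanes were balanced between treatments within each generation, but a recomputation within lanes was not possible from lists of group differences.

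Sites of one generation at most 1000 bp apart were merged into regions, and a region took the sign of its mean difference. The hypermethylated share was tested with a two-sided exact binomial test and its difference between generations with a two-sided Fisher's exact test. Intervals are 95% exact Clopper-Pearson intervals over regions and cover counting error only. The median absolute difference of hyper- and hypomethylated regions was compared with a two-sided permutation test and the chromosome spread with a permutation test of the chi-square statistic, both with 100000 resamples. Adjacent sites at most 100 bp apart were compared in direction with 10000 shufflings. Sites with identical chromosome, position and strand were counted as shared, and shared sites were merged by the same distance before directions were tested. Families of 3 tests were adjusted by the Benjamini-Hochberg method, and such p-values are called adjusted. The p-values for neighbouring sites and for agreement in being the same or opposite are given unadjusted.

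Sites were named by a rule: the 10 hypermethylated and 10 hypomethylated regions of each generation with the largest absolute difference at 1 site, up to 15 regions holding a site listed in at least 2 generations, and up to 10 regions per generation with at least 5 sites of one direction. These rules, the tests and the alternatives were chosen before the data were examined, except where the closing part says otherwise. The planned gene context of sites and the planned counts over named gene lists were not run, because no annotation of Rnor_5.0 was used here and the lists hold no gene names.

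For shared regions 2000 bp to 1 Mb apart, the log2 ratio of the absolute differences of 2 generations was correlated over pairs of regions, each pair entered in both orders, with 10000 shufflings of values among regions (one-sided). The same was done for the absolute difference within a generation. A mean product of values standardised over all regions was also calculated for both. It also rises where paired regions are larger than other regions, as described with its simulation below. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.

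The tests were tested on simulated data of the same size, with 200 sets per case and 400 shufflings each. With no difference simulated, the permutation test of medians gave p at or below 0.05 in 3.5% of sets for F1, 6% for F2 and 5.5% for F3, and with hypermethylated regions larger by 2 points in 99%, 81.5% and 98.5%. For shuffled log ratios the pair correlation passed in 6% of sets for F1 and F2, 2.5% for F1 and F3 and 4.5% for F2 and F3, and with block and independent parts of equal variance in 87%, 97.5% and 98%. For sizes simulated as larger where regions are dense but otherwise independent, the pair correlation passed in 11.5%, 25% and 19% of sets for F1, F2 and F3, and the mean product in 67%, 71.5% and 79%.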

Results

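DNA methylation was measured by reduced representation bisulfite sequencing, which reads CpG-rich fragments of the genome after bisulfite has converted unmethylated cytosines, in epididymal sperm of Sprague-Dawley rats. Founder females (F0) received by gavage either corn oil or an Arctic mixture of persistent organic pollutants, named organochlorines in the labels, at 500 µg per kg body weight, and dosing went on through mating until parturition. The labels describe 48 sperm samples in 8 groups of 6, a control and an organochlorine group in each of 4 labelled generations. Males of the F1, F2 and F3 generations were killed at 90 days of age, per the labels' protocols. The sequencing lanes were balanced: each group had 3 samples on each of its lanes, in both treatments. Labelled generations 1 and 2 shared their lanes, and generations 3 and 4 shared other lanes, so lane and generation were separated within each of these pairs and not between them.

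The values analysed were 6 deposited lists of differentially methylated cytosines, a hypermethylated and a hypomethylated list for each of 3 comparisons between control and treatment. The lists are described as generations F1, F2 and F3, whereas the labels number generations 1 to 4, and the names of the lists are used here. The description does not say which group was subtracted from which, so hypermethylated and hypomethylated are used in the lists' own sense. Each value is the authors' group difference, so no replicate spread could be calculated and the depth behind each site is unknown. Positions are on the rat build Rnor_5.0, and no annotation of that build was used here, so sites are named by position only.

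The first question was how many cytosines differed between the exposed and control lines in each generation, and in which direction. The F1 lists held 1721 cytosines, of which 1012 were hypermethylated and 709 hypomethylated. In F2 there were 1219 cytosines, 663 hypermethylated and 556 hypomethylated, and in F3 there were 1997, with 936 hypermethylated and 1061 hypomethylated. The number of cytosines tested in each generation was not given. Numbers read from the p- and q-values in the closing part rank the generations in the same order, so these counts do not show which generation changed most. After cytosines at most 1000 bp apart were merged, F1 had 1283 regions, F2 had 831 and F3 had 1392. Single cytosines made up 82.3% of the F1 regions, 75.9% of the F2 regions and 75.6% of the F3 regions.

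Hypermethylated regions were in the majority in F1 and in the minority in F3, in the lists' own sense. Hypermethylated regions numbered 818 in F1, a share of 63.8% (95% exact Clopper-Pearson interval 61.1% to 66.4%). This share differed from an equal split in a two-sided exact binomial test (Benjamini-Hochberg adjusted p = 1.4e-22). In F2 the 460 hypermethylated regions made up 55.4% (51.9% to 58.8%, exact binomial test, adjusted p = 0.0034). In F3 the 650 hypermethylated regions made up 46.7% (44.0% to 49.4%, exact binomial test, adjusted p = 0.015), so hypomethylated regions were in the majority. If the lists subtract treatment from control, these shares turn over, and regions with higher methylation in the treated lines would make up 36.2% in F1, 44.6% in F2 and 53.3% in F3. With a minimum difference of 25 percentage points, F1 passed the test at 58.3%, but F2 at 52.7% and F3 at 46.9% did not. At q of at most 1e-5, F1 passed at 61.4%, but F2 at 53.5% and F3 at 48.6% did not. With a minimum difference of 30 percentage points, none of the 3 shares passed the test: F1 had 55.8%, F2 had 49.3% and F3 had 48.1%. Among regions with at least 2 sites the shares of 52.0%, 56.5% and 48.1% did not pass either.

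**Figure D1:**
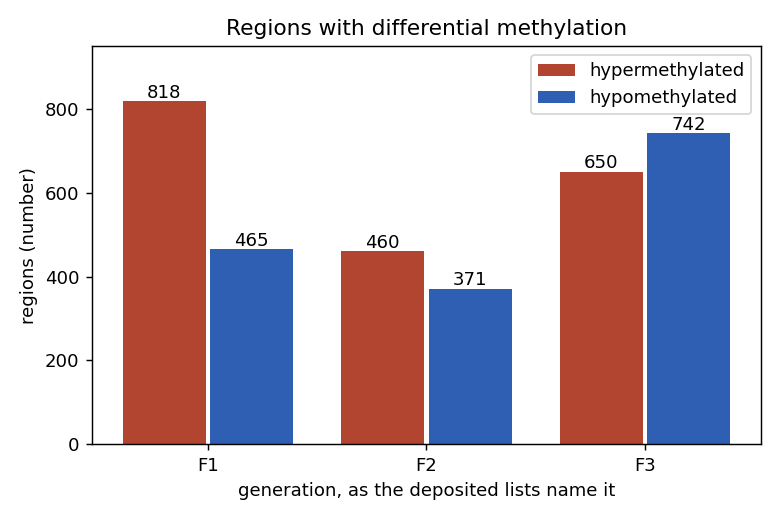
Number of hypermethylated and hypomethylated regions (vertical axis) in the F1, F2 and F3 lists (horizontal axis), with cytosines at most 1000 bp apart merged. Hypermethylated regions numbered 818, 460 and 650 and hypomethylated regions 465, 371 and 742.

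This balance was then compared between the lists of the generations. Each generation gave 1 group contrast, so these p-values cover the counting of regions only. They do not cover differences between animals or anything else common to 1 contrast. The hypermethylated share was 17.1 percentage points higher in F1 than in F3 by two-sided Fisher's exact test (adjusted p = 2.6e-18). It was 8.40 points higher in F1 than in F2 (Fisher's exact test, adjusted p = 0.00013) and 8.66 points higher in F2 than in F3 (adjusted p = 0.00012). With a minimum difference of 25 points, F1 minus F3 was 11.4 points and passed the test. F1 minus F2 was then 5.60 and F2 minus F3 5.81 points, and neither passed. With a minimum difference of 30 points, the differences for F1 minus F3, F1 minus F2 and F2 minus F3 were 7.74, 6.52 and 1.22 points and none passed. Over regions with at least 2 sites none passed either, and F1 minus F2 turned to -4.52 points (Fisher's exact test, adjusted p = 0.39). F1 minus F2 was 4.41 points on single sites, and F2 minus F3 was 4.92 points at q of at most 1e-5 and 13.6 points without recurrent regions, all past the test.

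Hypomethylated regions had somewhat larger differences than hypermethylated regions in F1 and F2, and no difference in size passed the test in F3. In F1 the median absolute difference was 24.4 percentage points in hypermethylated regions and 26.5 in hypomethylated regions, a difference of -2.15 points (two-sided permutation test, adjusted p = 9e-05). In F2 the medians were 25.9 and 27.3 points, a difference of -1.35 (permutation test, adjusted p = 0.048), and in F3 they were 26.1 and 25.9 points, a difference of 0.21 (adjusted p = 0.55). The F2 difference did not pass after merging at 10000 bp, where it was -1.15 points, nor at q of at most 1e-5, where it was -1.26, and it was -3.003 points with the largest difference of each region (permutation test, adjusted p = 0.0023). All lists begin at 20 points, so these medians describe listed regions and not all cytosines measured.

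The strongest single sites reached differences above 70 percentage points in each generation. In F1 the authors' deposited table gave -79.7 points at chromosome 17, position 11662290, and 70.6 points at chromosome 17, position 91272438. In F2 the authors' deposited table gave -83.7 points at chromosome 11, position 29043818, and 71.0 points at chromosome 16, position 45902208. For F3 the authors' deposited table gave -84.9 points at chromosome 1, position 144325212, and 76.7 points at chromosome 8, position 19727519. Further down the F1 ranking, the authors' deposited table gave 63.3 points at chromosome 12, position 40199696, and -66.9 points at chromosome 10, position 18631999. The F2 ranking of the authors' deposited table continued with 67.2 points at chromosome 10, position 14760342, and -70.0 points at chromosome 17, position 15275237. The F3 ranking of the authors' deposited table continued with 69.7 points at chromosome 8, position 130854237, and -71.7 points at chromosome 12, position 30057469.

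Leading regions often held a listed site in another generation too. The rankings of the 3 generations named 57 distinct leading regions, 3 of them in 2 generations, and 40 of the 57 held such a site. Among the 10 hypermethylated regions with the largest differences this was so for 8 in F1, 9 in F2 and 7 in F3. Among the 10 hypomethylated regions it was so for 5 in F1, 7 in F2 and 7 in F3. Over all regions the shares were 29.0%, 47.4% and 35.1% of hypermethylated regions in F1, F2 and F3, and 44.5%, 55.0% and 31.8% of hypomethylated regions. The difference between leading regions and all regions was not tested. The deposited q-value was 0 at the leading site of every one of these regions, so q did not rank them.

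Some regions carried long runs of sites with one direction. On chromosome 6, from 144720006 to 144720227, the authors' deposited table listed 29 hypomethylated sites in F1 with a mean difference of -43.1 points. The same interval of the authors' deposited table held 28 hypomethylated sites in F2 with a mean of -27.2 points and no site in F3. On chromosome 12, from 25996483 to 25997144, the authors' deposited table held 39 hypermethylated sites in F3 with a mean of 32.1 points, against 1 site in F1. On chromosome 1, from 26238524 to 26238659, the authors' deposited table held 13 hypomethylated sites in F2 and 13 in F3, with means of -27.7 and -32.6 points. On chromosome 13, from 57960469 to 57960614, the authors' deposited table held 16 hypomethylated sites in F3 with a mean of -38.6 points, with 8 sites in F2 and 4 in F1, all in the same direction. Chromosome 17, from 91224532 to 91224679, held 8 hypomethylated sites in F1 and 8 in F3 in the authors' deposited table, with means of -56.2 and -30.2 points. A run of 22 hypomethylated sites on chromosome 10, from 43465411 to 43465582, with a mean of -31.5 points in the authors' deposited table, was listed in F1 alone.

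As an internal check of the lists, neighbouring cytosines were compared, and they nearly always had the same direction. Such cytosines can be read by the same fragments and are not independent, so agreement above shuffling was likely beforehand. Of adjacent listed pairs at most 100 bp apart, 93.5% of 413 in F1, 96.0% of 372 in F2 and 95.1% of 572 in F3 shared their direction. After directions were shuffled among sites, the means were 51.5%, 50.3% and 50.2% (one-sided permutation p = 1e-04 in each generation, the smallest that 10000 shufflings can give). Among these pairs were the 2 strands of one CpG, which had the same direction in 141 of 145 pairs in F1, 113 of 113 in F2 and 237 of 241 in F3.

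The next question was whether the same cytosines were listed again in a later generation. Of 3998 distinct cytosines in the lists, 3190 were listed in 1 generation, 677 in 2 and 131 in all 3. F1 and F2 shared 344 cytosines, F1 and F3 shared 381, and F2 and F3 shared 345. These made up 20.0% of the F1 sites and 28.2% of the F2 sites for the first pair, and 22.1% of the F1 sites and 19.1% of the F3 sites for the second. The set of cytosines that could be called in each generation was not given in the sources used here, so no test against chance overlap was made.

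Shared sites mostly kept their direction, more so between adjacent generations than between F1 and F3. The 344 sites shared by F1 and F2 lay in 258 regions, of which 241 had the same direction in both, a share of 93.4% (95% interval 89.7% to 96.1%, two-sided exact binomial test against an equal split, adjusted p = 2.3e-51). For F2 and F3 the direction was the same in 246 of 281 regions, or 87.5% (83.1% to 91.2%, exact binomial test, adjusted p = 4.8e-40). For F1 and F3 it was the same in 222 of 302 regions, or 73.5% (68.2% to 78.4%, exact binomial test, adjusted p = 1.3e-16), and opposite in the remaining 80. The share was lower by Fisher's exact test for F1 and F3 than for F1 and F2 (adjusted p = 4.6e-10) and than for F2 and F3 (adjusted p = 4e-05). Cytosines listed in all 3 generations enter both sides of these comparisons. Regions near one another also tended to agree in being the same or opposite, as given in the closing part. Regions are therefore not independent in these tests or in the binomial tests, and the p-values are only rough. Of the 131 cytosines in all 3 generations, 114 kept one direction throughout, 56 of them hypermethylated and 58 hypomethylated.

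**Figure D2:**
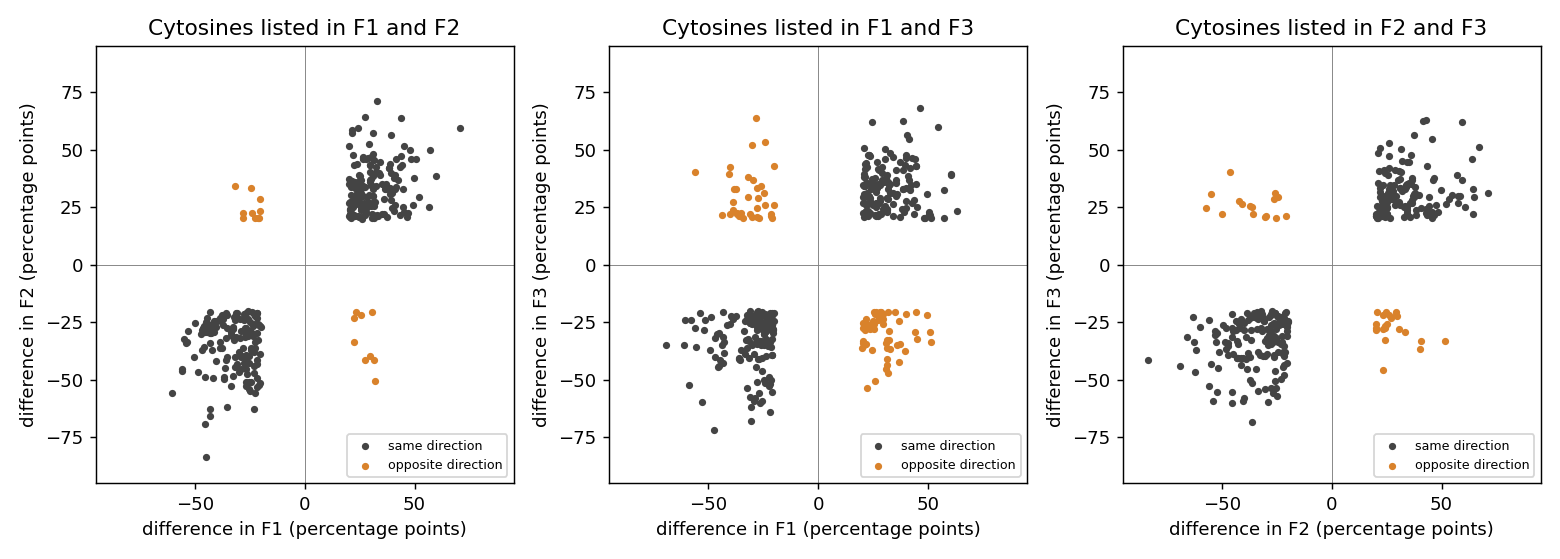
Methylation difference at cytosines listed in a pair of generations, in percentage points, with the earlier generation on the horizontal axis and the later one on the vertical axis, and one point per cytosine. Sites with opposite directions number 19 for F1 and F2, 89 for F1 and F3 and 38 for F2 and F3. The empty band around 0 comes from the 20-point minimum of the lists.

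Several of the largest differences belonged to recurrent sites. The F2 site on chromosome 11, position 29043818, was at -44.9 points in F1 and -41.5 points in F3 in the authors' deposited table. The hypermethylated F2 site on chromosome 16, position 45902208, was at 32.9 points in F1 and 31.1 points in F3 in the authors' deposited table. On chromosome 12, position 39426529, the authors' deposited table gave -45.3, -69.1 and -44.1 points in F1, F2 and F3. Chromosome 11, position 28401647, was hypermethylated throughout in the authors' deposited table, at 43.9, 63.9 and 45.8 points. Of the 40 distinct leading regions listed again, 3 had the opposite mean direction in another generation. Regions with only some sites of the opposite sign were not counted. In the authors' deposited table, chromosome 4, position 13461000, was at -55.8 points in F1, -46.1 in F2 and 40.2 in F3. Position 22667502 of chromosome 4 was at -57.3 points in F2 and 24.6 in F3 in the authors' deposited table, and the other strand of this CpG was at -21.8 in F1. Position 18003582 of chromosome 10 was at -28.3 points in F1 and 63.6 in F3 in the authors' deposited table.

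Regions fell on all 20 chromosomes listed, in proportions that differed between generations (chi-square 74.0 over 3506 regions, permutation p = 0.00054). The test treated regions as independent, but 34.6%, 50.8% and 33.3% of the F1, F2 and F3 regions held a site listed in another generation. The cytosines that could be called on each chromosome were not known either, so this p-value is only rough. Chromosome 7 held 90 regions or 7.01% in F1, 56 or 6.74% in F2, and 48 or 3.45% in F3. Chromosome 16 held 3.35% of the F1 regions, 5.78% of the F2 regions and 4.02% of the F3 regions. These 2 chromosomes were chosen after their values were seen, and single chromosomes were not tested.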

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

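The tests of blocks of linked regions and of merging at 1 Mb were chosen after the lists had been examined. The hypermethylated share of regions differed between all pairs of generations by Fisher's exact test, by 17.1 percentage points for F1 minus F3, 8.40 for F1 minus F2 and 8.66 for F2 minus F3. Shared regions with opposite directions numbered 80 for F1 and F3, 35 for F2 and F3 and 17 for F1 and F2. The reversal at single regions was not tested, because the lists hold no values of samples.

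A few blocks of linked regions counted many times could produce a different share of hypermethylated regions in F1 and F3. After merging at 1 Mb the share was still 20.4 points higher in F1 (Fisher's exact test, p = 2e-12), which argues against this as the whole cause. Exposure, line and generation remain open as untested explanations, as does a difference in depth between generations, since the depth is unknown. Labelled generations 1 and 2 were on other sequencing lanes than generations 3 and 4, so a difference between F1 and F3 is confounded with lane, under either reading of the generation numbers.

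For the regions with opposite directions in F1 and F3, false calls near the minimum difference would give smaller differences. The median of the smaller absolute difference was 23.7 points in the 80 opposite regions and 24.4 in the 222 others, a difference of -0.71 points (permutation p = 0.39), so such false calls cannot be told apart by size in lists that begin at 20 points. Shared regions near one another tended to agree in being the same or opposite, which does not bear on such false calls. Of 56 blocks with at least 2 regions shared by F1 and F3, 35 were all the same, 11 all opposite and 10 mixed. Of 137 pairs of shared regions 2000 bp to 1 Mb apart, 90.5% agreed in being both the same or both opposite, against a mean of 61.0% after shuffling (permutation p = 1e-04, the smallest that 10000 shufflings can give). This is consistent with blocks of linked regions that change together, as a hypothesis found and tested on the same data.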

How the results depend on the processing

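Merging at 1 Mb, leaving out recurrent regions, and comparing generations over regions with at least 2 sites were chosen after the data were examined. Of 99 alternative values over 19 results, 75 kept their side of the threshold or stayed within 1.5 times the count. Those with a direction kept it, except the F3 size difference. It passed in no setting and turned from 0.21 to -0.32 points at q of at most 1e-5. The other 24 follow, and the cause of these changes was not tested. Where fewer regions were left, lower power may be part of a lost test result. Several values themselves also moved toward an equal split or turned over, and the counts of shared sites carry no test. The hypermethylated share no longer passed in F1 at a minimum of 30 points (55.8%) and for regions with at least 2 sites (52.0%). In F2 it no longer passed at 25 points (52.7%), at q of at most 1e-5 (53.5%), with at least 2 sites (56.5%) and after merging at 1 Mb (54.4%), and fell below an equal split at 30 points (49.3%). In F3 it no longer passed at 25 points (46.9%), 30 points (48.1%), q of at most 1e-5 (48.6%) or at least 2 sites (48.1%). The difference between generations no longer passed at 30 points for F1 minus F3 (7.74 points), at 25 and 30 points for F1 minus F2 (5.60 and 6.52), and at 25 and 30 points for F2 minus F3 (5.81 and 1.22). Over regions with at least 2 sites it was 3.90 points for F1 minus F3 and 8.42 for F2 minus F3, neither past the test, and turned to -4.52 for F1 minus F2. Sites shared at 25 points fell to 196, 184 and 193. The F2 size difference no longer passed after merging at 10000 bp (-1.15 points) or at q of at most 1e-5 (-1.26), and passed with the largest difference of each region (-3.003). The direction of shared sites passed in every alternative run, with 69.7% to 76.9% for F1 and F3, and so did the chromosome spread and the agreement of neighbours. All chromosomes listed were autosomes, so that alternative was void, and those on gene context and gene lists were not run. No paired analysis was possible because the deposited lists hold no values of single samples, which also rules out leaving out replicates or other splits of the samples. Depth limits are unknown.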

Other observations

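The tests of log ratios between generations were chosen after recurrence had been seen. The direction of shared sites was a planned test, and setting it against unstable estimates was chosen afterwards; the tests of isolated sites and of size within a generation were written before their results. Some recurrent sites lay in blocks that held both hyper- and hypomethylated sites, and 2 examples were chosen here after their values were seen. Other blocks held 1 direction only, such as 4 hypermethylated cytosines on chromosome 8 between 21871606 and 22811961. On chromosome 12, between 38556483 and 39426529, 8 cytosines were listed in all 3 generations, 2 hypermethylated and 6 hypomethylated in F1. Their mean absolute differences in the authors' deposited table were 36.3 points in F1, 54.9 in F2 and 32.1 in F3. On chromosome 17, between 11662289 and 11749110, 3 such cytosines had means of 53.1, 49.1 and 22.3 points in the authors' deposited table. In F1, 1 was hypomethylated and 2 were hypermethylated, the latter being the 2 strands of 1 CpG. Another block on chromosome 17 went otherwise in the authors' deposited table. Its position 17819008 was at 20.4, 51.5 and -33.0 points in F1, F2 and F3, and position 17900260 was at -22.5, -55.8 and -52.8 points.

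The ratios p/q in the lists fell within 0.01 of whole multiples of a common step for 91.7% of distinct values in F1, 91.2% in F2 and 92.1% in F3. Read as ranks, these steps correspond to 859127, 658467 and 1023134, a reading drawn from the values and not from a stated method. These would be the numbers of tests, or, if the q-values were scaled by an estimated share of true nulls, those numbers times that share and so lower bounds. With the smaller number of each pair as the set of cytosines, independent lists would share about 3.19, 4.00 and 3.70 sites, against 344, 381 and 345 observed, and fewer still if the numbers are lower bounds. The common set of callable cytosines is not known, so these are rough figures and no test.

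A technical explanation of recurrence is that cytosines with unstable estimates recur whatever the group, which would give an equal split of directions. The lowest share with the same direction was 73.5%, past the exact binomial test in all 3 pairs, which argues against it as the whole cause.

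Variants at single cytosines only would make isolated regions recur at least as often as larger ones in each pair of generations. Isolated F1 regions recurred less often, in F2 at 17.5% against 25.1% (Fisher's exact test, p = 0.011, adjusted over 6 searches p = 0.034) and in F3 at 20.8% against 27.3% (Fisher's exact test, p = 0.034, adjusted p = 0.069). This met, in 2 of 3 pairs, the bound set beforehand on the unadjusted test, and in 1 pair after adjustment. The other searches did not all go the same way: F3 in F1 gave 18.7% against 23.0%, F2 in F1 29.2% against 26.5%, F3 in F2 18.2% against 17.7%, and F2 in F3 34.2% against 22.5% (Fisher's exact test, adjusted p = 0.0099). Regions with at least 3 shared CpGs of one direction held 12.8% of the CpGs shared by F1 and F2. They held 8.36% for F1 and F3 and 10.3% for F2 and F3, a count made after the lists had been examined. For F1 and F2, 27 of the 40 CpGs in such regions were 1 run over 222 bp on chromosome 6. Its shared sites were all on the plus strand, at positions in a regularly repeated pattern. The isolation test cannot decide on such variants, because a larger region can be both strands of 1 CpG and the 6 searches went both ways. Runs of at least 3 shared CpGs are more than single cytosines, but they held a small part of the shared CpGs. For the other shared CpGs such variants stay open.

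A candidate explanation is genotype differences between the control and exposed lines: in an outbred stock, a chromosome segment whose frequency differs between lines could carry higher methylation at some sites and lower at others. It predicts that the ratio of differences between generations is shared by neighbouring regions even where one was hypermethylated and the other hypomethylated. Over such pairs 2000 bp to 1 Mb apart the correlation of log2 ratios was 0.39 for F1 and F2 (53 pairs, adjusted p = 0.0018), 0.54 for F1 and F3 (56 pairs, adjusted p = 0.00015) and 0.57 for F2 and F3 (68 pairs, adjusted p = 0.00015). At 1 to 5 Mb it was 0.13, 0.04 and 0.09, and at 5 to 20 Mb it was 0.02, -0.14 and -0.07. Over pairs of any direction the correlation at 1 to 5 Mb was 0.11, 0.09 and 0.15 (one-sided shuffling test, unadjusted p = 0.029, 0.092 and 0.0056). At 5 to 20 Mb the correlation over pairs of any direction was 0.13, -0.09 and 0.002. For F1 and F2 it thus did not vanish with distance, and for F2 and F3 it was still seen at 1 to 5 Mb. All 5 forms of the test at 2000 bp to 1 Mb that were computed, on ranks, without small means and as a mean product, passed in all 3 pairs. The pairs of regions share members and are not independent. The shuffling held the pairs fixed, so this sharing is in the shuffled values too. It still treats every region as free to take any value, whatever its number of sites.

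The same hypothesis predicts that absolute differences correlate between neighbouring hyper- and hypomethylated regions within a generation. The prediction written beforehand named the measure, the absolute difference, and no statistic; the correlations of this measure were small: 0.13 in F1, 0.17 in F2 and 0.0845 in F3 (permutation test, adjusted p = 0.0012, 0.0012 and 0.0069). This outcome depended on the form. Of 7 forms computed, one after another and with earlier ones seen, 6 passed in at least 2 generations. On the log2 scale over all regions, none passed, with 0.02, 0.11 and 0.02 (permutation test, adjusted p = 0.274, 0.0513 and 0.274). Most regions with sites of both directions had small means, with a median absolute mean of 3.84, 3.60 and 3.28 points in F1, F2 and F3 and a maximum of 33.6, which the log scale stretches. Without them the log2 correlations were 0.15, 0.18 and 0.15 (adjusted p = 0.0002 in each). The leaving out of these regions was chosen after the log2 result was seen. Simulated sizes that only rose with the density of regions also passed too often, so this test may say little by itself.

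These results are consistent with line genotype as a hypothesis (lowest correlation of log ratios 0.39), and do not separate it from exposure. Exposed and control lines descend from different founders, so line and exposure are confounded here, and an inherited effect of exposure on linked regions stays open as untested. Genotypes were not analysed here.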
